A study of Homo sapiens with 3 samples.

How the data were processed

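RNA sequencing was done on 3 libraries of Hep3B cells, a human hepatocellular carcinoma line, with 1 library in each of 3 groups: a control, cells transfected with a plasmid encoding HKR3, and cells transfected with a small interfering RNA against TERT. HKR3 is an older name of ZBTB48, a zinc finger protein that binds telomeres. Groups were taken from the titles and treatment labels. The control label names the transfection reagent and, in the title, the words NT and Empty, so whether these cells received an empty plasmid, a non-targeting RNA or both is not given in the sources used here. Per the labels' protocols, RNA was extracted with TRIzol, and libraries were made with a stranded TruSeq kit for messenger RNA.

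The deposited table holds FPKM (fragments per kilobase of transcript, scaled by the size of the library) per gene and library, as the authors calculated it. Per the submitters' processing notes, STAR 2.5.0, Cufflinks and Cuffdiff 2.2.1 were used with the hg19 genome build. Which of these steps used which settings, whether strand was used in counting, and any filter on reads or genes are not given in the sources used here. FPKM divides out transcript length and library size. Whether library size was the count of mapped fragments, or was scaled further between libraries, is also not given. If it was that count, a gene that takes a large share of the fragments lowers the FPKM of the others. The table lists 19869 genes by Ensembl identifier. A table of gene names matched 19119 of them to a symbol, and 750 had none. The 10 entries that shared a symbol with another entry were summed. Short noncoding RNAs, 3 in the table, were left out of counts of genes. No coordinates are given, since the annotation at hand is for another genome build.

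Differences between libraries were calculated as log2(FPKM + 1), that is with a pseudocount of 1 FPKM, over the 10973 genes with a mean FPKM of at least 1 over the 3 libraries. On this scale the difference of a weakly expressed gene is understated. With 1 library per group there is no replicate check, so no p-value, SD or SE is given, and a size rule of 2-fold replaced a test. The named genes were ZBTB48 and TERT, the 10 genes with the largest and the 10 with the smallest difference in each comparison with the control, up to 4 members of each gene list with the largest absolute difference, and the 10 genes in each direction with the largest smaller value of the 2 differences. ALB, ATF5, DDIT3, FGA, FGB, FGG, GADD45A, NQO1, PHGDH, PSAT1, RB1 and SLC7A5 were named outside this rule, after their values were seen. The 37 gene lists, the size rule, the rule for named genes and the alternatives were fixed before the data were examined.

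For each list with at least 4 measured members, the median difference was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart when its median lay outside the central 95% of these. The result of 1 of the 33 measured lists is left out of the text. This percentile describes these libraries and is no test of the treatments. Both treated libraries were compared with the same control library, so 100 pairs of unchanged libraries were simulated against a shared control. They give the overlap, correlation and covariance that sharing it produces when all libraries deviate equally. The simulated spread came from the differences between the library labelled siTERT and the control. The method was tested on simulated data with 10872 genes. For the HKR3 comparison, 100 of 100 genes raised 8-fold and 46 of 46 lowered 8-fold were recovered, and 0 of 10674 unchanged genes were called. Lowered genes with a low control level were not counted among the 46. The simulated noise was smaller than the spread of the real differences across genes. The 0 is therefore no measure of false calls in these data. An 8-fold shift lies far past the 2-fold rule at this noise, so full recovery was set in advance. The recovered counts check the calculation only and are no measure of sensitivity. For the siTERT comparison, 7 of 200 unshifted random lists, or 3.5%, lay outside the central 95%.

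The number of fragments per library is not given in the sources used here. It was estimated from the FPKM worth of a single fragment in weakly expressed genes with 1 annotated transcript of at least 1000 bases, with transcript lengths from GENCODE v29. The estimates were 1.06e+07 fragments for the control, 1.21e+07 for the HKR3 library and 1.19e+07 for the library labelled siTERT. They rest on 63 of 103, 53 of 130 and 67 of 122 low genes whose value lay within 25% of 1 fragment. If FPKM was scaled further between libraries, the estimates are scaled sizes and not read depths. A comparison of low values between libraries gave a depth of 1.12 times the control for each treated library. The counting interval for TERT used exact binomial limits at 95% on fragments estimated from its shortest coding transcript of 3210 bases, and covers counting error only.

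Alternatives were pseudocounts of 0.1 and 5, scaling to a common median log ratio, scaling every library to the same sum (TPM), no filter on low values, a mean FPKM of at least 5, the highest entry per symbol, short noncoding RNAs kept, size rules of 1.5-fold and 4-fold, and the mean in place of the median of a list. Leaving out replicates was not possible. After the data were seen, further checks were added. Trends of the differences with GC content, transcript length and mean expression were removed with polynomials of degree 3. Genes with at least 50% of their 31-base sequences in another gene of the table, by GENCODE v29 transcripts, were left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.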

Results

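Gene expression was measured by RNA sequencing in Hep3B cells, a line derived from a human hepatocellular carcinoma, in a control library, a library from cells overexpressing HKR3 (ZBTB48) and a library labelled siTERT, for knockdown of TERT. TERT is the catalytic subunit of telomerase. Each group held 1 library, so no difference between groups could be set against a spread between replicates, and all values below are single measurements. The FPKM of all genes summed to 596536 in the control, 535516 in the HKR3 library and 579410 in the library labelled siTERT. At least 1 FPKM was reached by 10868, 10968 and 10878 genes in the same order. The 50 highest genes took 22.6%, 21.5% and 22.3% of the sum.

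The targeted genes were examined first, as a check of the labels. ZBTB48, the gene encoding HKR3, was at 4.91 FPKM in the control, 2842 FPKM in the HKR3 library and 4.89 FPKM in the library labelled siTERT. This was a 578-fold higher level in the HKR3 library, where ZBTB48 alone took 0.531% of the FPKM sum. Transcripts from the plasmid count only as far as the construct holds exons of the annotated gene. They were not separated from those of the cells' own gene. TERT was at 4.69 FPKM in the control, 4.25 FPKM in the HKR3 library and 5.37 FPKM in the library labelled siTERT. TERT was therefore not lower in the library labelled siTERT, and its ratio to the control on estimated fragments was 1.14, with a 95% counting interval from 0.925 to 1.42. In the HKR3 library that ratio was 0.905, from 0.723 to 1.13, so no difference in TERT was detectable at this depth. The log2 difference of TERT in the HKR3 library, -0.12 as deposited, was 0.01 after scaling every library to the same sum, as in TPM.

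The first comparison asked which genes differed between cells overexpressing HKR3 and the control. Immediate early genes and NF-kB target genes were higher as lists, while E2F-regulated replication genes and secreted hepatocyte proteins were lower as lists. CXCL8, a neutrophil-attracting chemokine, was at 1.96 FPKM in the control and 62.4 FPKM in the HKR3 library. JUN, a subunit of the AP-1 transcription factor, was at 8.49 and 146 FPKM. At least 2-fold differences were seen in 882 of 10973 genes, with 606 higher and 276 lower, so that 68.7% of them were higher. Scaling to TPM moved the median of all genes by 0.14 in log2 and gave 991 higher and 207 lower genes, or 82.7% higher, and a pseudocount of 5 gave 238 and 92. At the other end, 72.0% of genes lay within 1.5-fold of the control.

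After ZBTB48 and the genes above, the largest differences were those of VNN3P, ANXA1, DUSP8, ATF3, CXCL2, AKR1C2 and CYP1A1. ANXA1, which encodes annexin A1, went from 0.798 to 25.6 FPKM. DUSP8, a phosphatase of MAP kinases, went from 0.534 to 20.5 FPKM. AKR1C2 and CYP1A1 encode enzymes that act on steroids and xenobiotics, and were at 2.82 and 43.1 FPKM, and at 8.41 and 101 FPKM. AKR1C2 shares 47.3% of its sequence with its neighbour AKR1C1 in units of 31 bases, so the split between the pair is uncertain, but their sum was 14.1 FPKM in the control and 98.3 FPKM in the HKR3 library. VNN3P is listed as a pseudogene of the vanin family, and was at 1.63 and 40.9 FPKM.

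Among the lowest genes were CHAC1, PAQR4, MYCN, CLEC2L, H2BC3, FHIT and SLC6A14. CHAC1, a glutathione-degrading enzyme, was at 22.4 FPKM in the control and 3.67 FPKM in the HKR3 library. MYCN, a transcription factor of the MYC family, was at 50.2 and 12.1 FPKM, and SLC6A14, an amino acid transporter, at 56.1 and 14.7 FPKM. PAQR4 was at 11.5 and 1.75 FPKM, and CLEC2L at 23.7 and 5.34 FPKM. H2BC3, a histone gene, and FHIT were weakly expressed, at 4.14 and 0.371 FPKM and at 3.93 and 0.320 FPKM. The other 3 of the 10 lowest genes had no symbol. The lowest of all of these, ENSG00000273590, has 90.5% of its sequence in SMIM11, and the sum of both was 8.98 FPKM in the control and 6.48 FPKM in the HKR3 library, a log2 difference of -0.42.

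Of 33 lists with enough measured members, 10 stood above and 8 below the random lists in the HKR3 library. For lists of unrelated genes, 1.65 would lie outside. Lists of genes regulated together, or with shared members, can lie outside more often, so 1.65 is no reference for a treatment effect. In the library labelled siTERT, 9 stood above and 9 below. Of 20 immediate early genes, 16 were at least 2-fold higher, with a median log2 difference of 1.83 at percentile 100 among 10000 random lists. DUSP1 was at 17.8 and 179.9 FPKM, ATF3 at 2.25 and 38.4 FPKM, and KLF4 at 0.315 and 7.76 FPKM. Of 16 NF-kB target genes, 9 were at least 2-fold higher, with a median of 1.28 at percentile 100. CXCL2, a chemokine, was at 28.8 FPKM in the HKR3 library with a log2 difference of 3.57, TNFAIP3, an inhibitor of NF-kB signalling, was at 2.15 and 24.2 FPKM, and RELB, an NF-kB subunit, at 3.82 and 30.7 FPKM. Of 17 TGF-beta and YAP/TAZ target genes, 10 were at least 2-fold higher, with a median of 1.06 at percentile 100. ANKRD1 was at 0.123 and 9.23 FPKM, TGFB2 at 2.25 and 14.6 FPKM, CCN1 at 14.3 and 61.3 FPKM, and BMP4 at 9.24 and 26.1 FPKM. ATF3 and CCN1 each belong to more than 1 list. The interferon-stimulated list had a median of 0.31 at percentile 95.3 and did not stand apart, with 3 of 16 members, IFIT2, ISG20 and CXCL10, at least 2-fold higher.

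Antioxidant genes regulated by NRF2 had a median of 0.65 in the HKR3 library, at percentile 100, with 7 of 18 at least 2-fold higher. GCLC, a subunit of the enzyme that limits glutathione synthesis, was at 11.1 and 47.7 FPKM, and AKR1B10 was at 1.42 and 14.5 FPKM. NQO1, another member, was at 695 FPKM in the control and 503 FPKM in the HKR3 library. Cholesterol synthesis genes had a median of 0.34 at percentile 100, with INSIG1 at 33.8 and 82.4 FPKM and HMGCS1, an enzyme of the mevalonate pathway, at 304 and 684 FPKM. The list of cytochromes P450, conjugation and bile acid genes had a median of 0.66 at percentile 98.8, with 6 members measured. CYP1A1 and the canalicular transporter ABCC2, at 25.4 and 58.4 FPKM, were at least 2-fold higher, while CYP27A1 was at 15.9 and 7.68 FPKM.

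**Figure D1:**
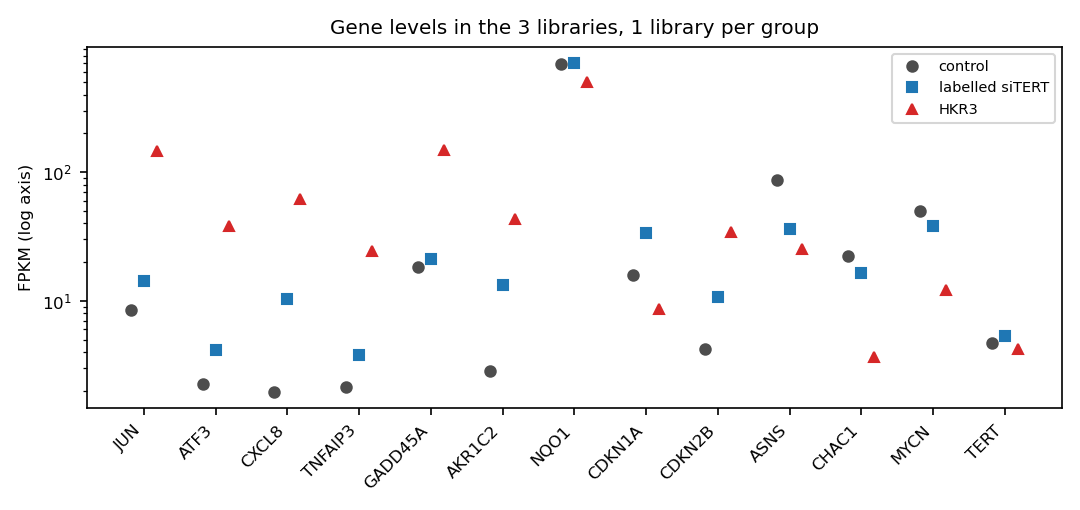
FPKM of 13 genes on a log axis in the control library (circles), the library labelled siTERT (squares) and the HKR3 library (triangles), 1 library each. JUN, ATF3 and CXCL8 sit highest in the HKR3 library, ASNS, CHAC1 and MYCN lowest there, and TERT lies between 4.25 and 5.37 FPKM in all 3 libraries.

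Of 38 E2F-regulated replication genes, 10 were at least 2-fold lower in the HKR3 library and 2 were above 0, with a median of -0.54 at percentile 0. PCNA, the sliding clamp of DNA polymerases, was at 191 and 73.8 FPKM, and E2F2, POLA2 and UHRF1 had log2 differences of -1.48, -1.42 and -1.41. Cyclins and kinases of G1 had a median of -0.48 at percentile 0.9, and CCNE1, cyclin E1, was at 9.58 and 2.96 FPKM, the 1 member of 10 at least 2-fold lower. This list no longer stood apart with a pseudocount of 5. Homologous recombination genes had a median of -0.30 at percentile 0.5, and -0.58 with the trends removed, with EXO1 at 11.5 and 4.10 FPKM. Mitotic genes had a median of -0.03 at percentile 70.4, a sign that turned after scaling to TPM, and 1 of 37, CDK1, was at least 2-fold lower, at 55.2 and 20.4 FPKM. Inhibitors of cyclin-dependent kinases went both ways, so that their median was -0.10 and their mean 0.28, and the median turned to 0.05 after scaling to TPM. CDKN2B, encoding p15, was at 4.24 and 34.4 FPKM and CDKN1B, encoding p27, at 27.4 and 66.3 FPKM, while CDKN1C was at 6.70 and 2.41 FPKM.

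The integrated stress response list had 5 of 27 members at least 2-fold higher and 6 at least 2-fold lower in the HKR3 library, with a median of -0.42 at percentile 0.19. The median lay inside the random range with a pseudocount of 5 or a mean FPKM of at least 5, and the list's mean of -0.01 did not stand apart. The higher members were ATF3, ATF5, DDIT3, PPP1R15A and GDF15. PPP1R15A, a regulator of the eIF2 alpha phosphatase, was at 21.7 and 167 FPKM, and GDF15, a stress-induced cytokine, at 39.8 and 237 FPKM. The lower members were CHAC1 and the amino acid genes ASNS, PSAT1, PHGDH, PSPH and SLC7A5. ASNS, asparagine synthetase, was at 86.8 and 25.3 FPKM, and PHGDH, the first enzyme of serine synthesis, was at 236 and 106 FPKM. CDKN1A, encoding the kinase inhibitor p21, was at 15.8 FPKM in the control and 8.71 FPKM in the HKR3 library. Apoptosis regulators had a median of 0.28 at percentile 98.5, with BBC3 and PMAIP1, encoding PUMA and NOXA, at least 2-fold higher, but this list no longer stood apart by its mean, without the expression filter or with the trends removed.

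Secreted hepatocyte proteins were lower as a list in the HKR3 library. Of 31 secreted plasma proteins and apolipoproteins, 4 were above 0 and 3 were at least 2-fold lower, with a median of -0.53 at percentile 0.01, which was -0.35 with the trends removed. APOA1, the main protein of high-density lipoprotein, was at 1461 and 713 FPKM, plasminogen (PLG) at 24.9 and 11.5 FPKM, and AGT, angiotensinogen, at 97.1 and 47.6 FPKM. ALB, albumin, was at 3317 and 2703 FPKM. The fibrinogen genes FGA, FGB and FGG, singled out after their values were seen, were above the control, with log2 differences of 0.48, 0.59 and 0.41. Liver-enriched transcription factors had a median of 0.35 at percentile 99.2, with NR5A2, PROX1 and FOXA2 at least 2-fold higher and PPARA at 5.57 and 2.45 FPKM, but the list's mean did not stand apart. Acute-phase genes had a median of -0.31 at percentile 13.3, and HP, haptoglobin, was at 51.1 and 26.2 FPKM.

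Glycolytic enzymes had a median of -0.50 in the HKR3 library at percentile 0.69 with no member past 2-fold. PFKL, a phosphofructokinase, was at 58.3 and 29.9 FPKM, and TPI1 at 1004 and 597 FPKM. Nuclear-encoded subunits of oxidative phosphorylation had a median of -0.48 at percentile 0.02, with 0 of 39 members above 0, and NDUFA8 at 61.2 and 26.7 FPKM. Genes with a mean of at least 300 FPKM had a median log2 difference of -0.33 in the HKR3 library, and those between 1 and 3 FPKM a median of 0.07. With trends with expression, GC content and transcript length removed, both lists still stood apart, glycolysis with a median of -0.37 and oxidative phosphorylation with -0.31. Ribosomal protein genes, with a median of -0.29 at percentile 65.0, lay inside the range of random lists of such highly expressed genes. The 13 protein genes of the mitochondrial genome were listed at 0 in all libraries, which is not read as absence. Lists of stromal and endothelial markers and of nonpolyadenylated RNAs also had 0 measured members, and immune markers had 3, LYZ, CD14 and CD68, too few for a median.

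Metallothioneins, small metal-binding proteins, had a median of -0.98 in the HKR3 library at percentile 0, with 3 of 7 at least 2-fold lower and 0 above 0. MT1G was at 104 and 43.1 FPKM and MT1E at 178 and 83.9 FPKM. Polyadenylated histone genes had a median of 0.32 at percentile 98.8, with H2BC21 at 3.17 and 10.4 FPKM, and epithelial-mesenchymal and matrix genes a median of 0.23 at percentile 98.6, with ZEB1 at 2.72 and 8.69 FPKM and ITGA5 at 3.36 and 1.01 FPKM. Both lists were inside the random range with a mean FPKM of at least 5, and the latter also by its mean, although its median was 0.48 with the trends removed.

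The following lists were inside the random range in the HKR3 library. Components of telomerase, shelterin and CST had a median of -0.11 at percentile 27.2, which turned to 0.01 after scaling to TPM. ACD, the shelterin protein TPP1, was at 27.0 and 12.1 FPKM, and NHP2, a core protein of telomerase, at 218 and 109.9 FPKM. Of genes reported elsewhere as ZBTB48 targets, 4 were measured, with a median of -0.54 at percentile 3.65, and the list stood apart without the expression filter. CDKN2A was at 78.5 and 51.7 FPKM and MTFP1 at 46.4 and 33.0 FPKM. Beta-catenin targets had a median of -0.33 at percentile 4.47, with DKK1, a secreted Wnt inhibitor, at 55.6 and 21.7 FPKM. Hypoxia genes had a median of -0.17 but a mean just above 0, with ADM and KDM3A at least 2-fold higher. Small medians that changed sign after scaling to TPM were those of ribosome biogenesis genes (-0.08), endoplasmic reticulum chaperones (-0.04), heat shock genes (-0.04), fatty acid synthesis genes (-0.15) and housekeeping genes (-0.14). Within them, CALR was at 708 and 511 FPKM and BAG3 at 14.2 and 29.7 FPKM.

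**Figure D2:**
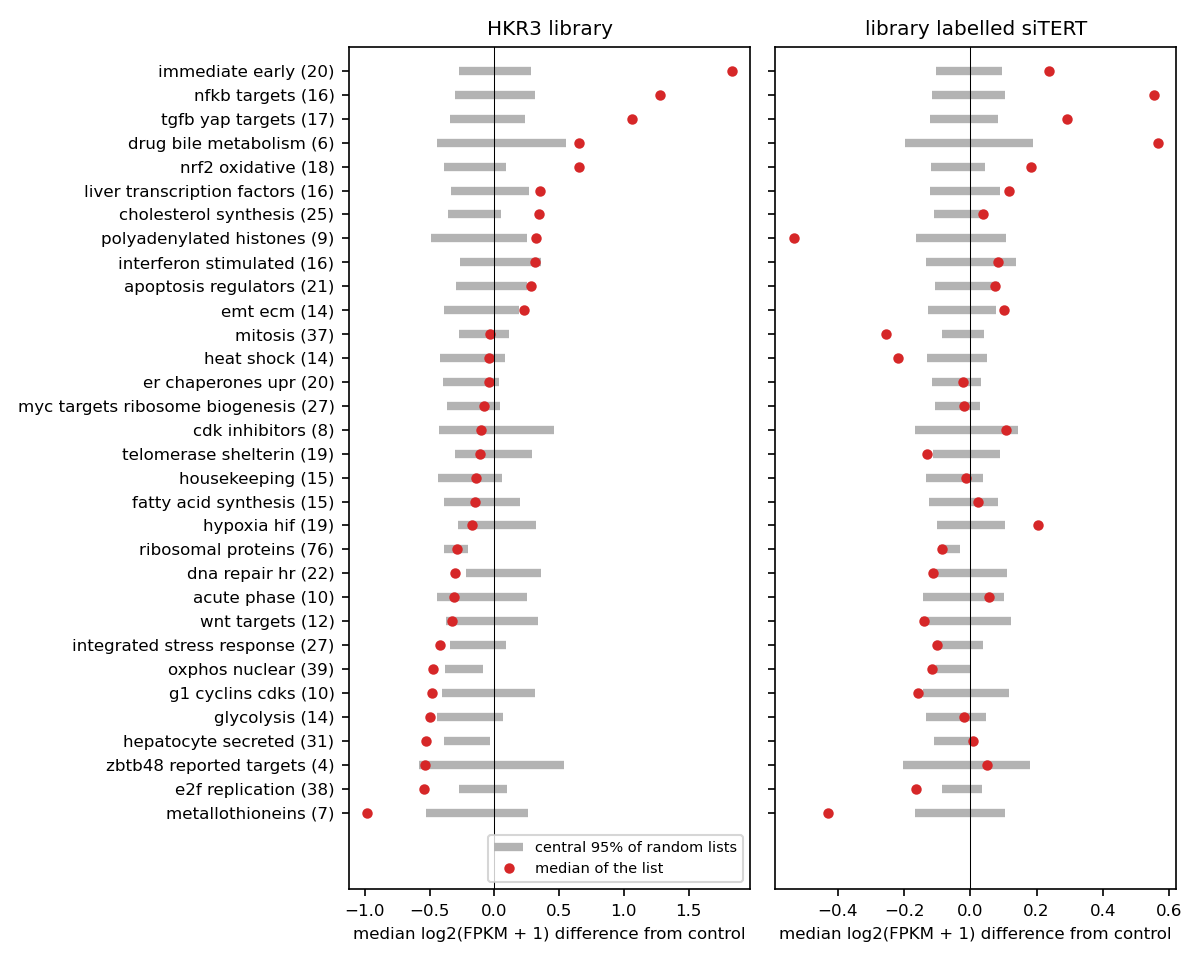
Median log2(FPKM + 1) difference from the control of gene lists (red points, number of measured members in parentheses) and the central 95% of matched random lists (grey bars), in the HKR3 library (left) and the library labelled siTERT (right), on different axis ranges. Immediate early genes lie at 1.83 on the left and 0.24 on the right, and polyadenylated histones at 0.32 on the left and -0.53 on the right.

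The comparison of the library labelled siTERT with the control was meant to show the effect of TERT knockdown. TERT was not lower in this library, so the directions below belong to the label and not to a measured loss of TERT. Few genes differed. CXCL8 was at 1.96 FPKM in the control and 10.3 FPKM in the library labelled siTERT, and ASNS was at 86.8 and 36.2 FPKM. CDKN1A was at 15.8 and 33.7 FPKM. At least 2-fold differences were seen in 53 genes, 31 higher and 22 lower, and 97.1% of genes lay within 1.5-fold of the control. These counts were 103 and 57 with a pseudocount of 0.1, 10 and 3 with a pseudocount of 5, and 47 and 27 after scaling to TPM.

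With TERT not lower, the highest genes in the library labelled siTERT with a symbol were SIK1, CXCL8, AKR1B10, AKR1C2, PIP4P2, BCL2L2-PABPN1, UBD and IL32. AKR1B10, a reductase of aldehydes, was at 1.42 and 8.16 FPKM, and AKR1C2 at 2.82 and 13.3 FPKM, with a sum of AKR1C2 and AKR1C1 of 14.1 and 42.4 FPKM. UBD, a ubiquitin-like modifier also known as FAT10, was at 6.52 and 21.8 FPKM, and the cytokine gene IL32 was at 6.16 and 19.6 FPKM. SIK1, a salt-inducible kinase, was at 0.0215 and 3.29 FPKM, but 87.3% of its sequence lies in ENSG00000275993, which was at 26.0 and 22.4 FPKM. The sum of these was 26.0 FPKM in the control and 25.7 FPKM in the library labelled siTERT, a log2 difference of -0.02. The gene with the largest difference in this library, ENSG00000280071, likewise shares 84.8% of its sequence with GATD3, and their sum was 33.8 and 30.6 FPKM. BCL2L2-PABPN1 is a read-through gene that shares 92.8% of its sequence with other genes.

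In the library labelled siTERT, where TERT was not lower, the 10 lowest genes included 5 with a histone gene symbol. H2BC3 was at 4.14 FPKM in the control and listed at 0 in the library labelled siTERT. H2AC12, H3C7, H2AC13 and H4C16 had log2 differences of -1.74, -1.64, -1.58 and -1.24, at a mean of few FPKM, and H2AC13 shares 63.8% of its sequence with H2AC14. FHIT, a diadenosine triphosphatase at a fragile site, was at 3.93 and 0.349 FPKM. FMC1-LUC7L2, a read-through gene, was at 3.42 FPKM and below 0.001 FPKM, and has 98.3% of its sequence in other genes. Of the genes with a transcript sequence, 10 of 30 higher and 6 of 21 lower genes had at least 50% of their sequence in another gene, against 204 of 10948 tested genes, or 1.86%. Without them, 21 genes were higher and 16 lower in the library labelled siTERT. TERT was not lower there.

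Of 33 lists, 9 stood above and 9 below the random lists in the library labelled siTERT, mostly with medians far under 2-fold, and again without a lower TERT. NF-kB targets had a median of 0.55 at percentile 100, with 14 of 16 above 0, and CXCL1 was at 8.24 and 19.6 FPKM. Immediate early genes had a median of 0.24 at percentile 100, and DUSP5, a phosphatase of ERK, was the 1 of 20 past 2-fold, at 67.2 FPKM with a log2 difference of 1.09. The TGF-beta and YAP/TAZ list had a median of 0.29 at percentile 100, with SMAD7 at 6.18 and 12.8 FPKM. NRF2-regulated genes had a median of 0.18 at percentile 100, with AKR1B10, AKR1C2 and AKR1C1 past 2-fold, and the drug and bile metabolism list a median of 0.57, also at percentile 100, with CYP1A1 at 8.41 and 20.3 FPKM. The latter stood apart on 6 measured members and not without the expression filter, where its median was 0.02. Hypoxia genes had a median of 0.21 at percentile 99.98, with PFKFB3 at 10.3 and 16.8 FPKM and NDRG1 at 52.3 and 78.8 FPKM, but did not stand apart without the filter, and the median was 0.14 with the trends removed. Liver transcription factors (0.12), epithelial-mesenchymal and matrix genes (0.10) and cholesterol synthesis genes (0.04) stood above by small amounts. The first no longer did so by its mean, the second without the filter and the third with the trends removed.

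In the library labelled siTERT, in which TERT was not lower, mitotic genes had a median of -0.26 at percentile 0 with no member past 2-fold and 2 of 37 above 0, and AURKB, a kinase of chromosome segregation, was at 88.7 and 59.4 FPKM. E2F-regulated replication genes had a median of -0.16 at percentile 0, with GINS2 at 28.9 and 20.6 FPKM. Polyadenylated histone genes had a median of -0.53 at percentile 0, with H2AC6 at 36.4 and 20.3 FPKM, and metallothioneins a median of -0.43 at percentile 0, with MT1G at 104 and 62.0 FPKM. Heat shock genes had a median of -0.22 at percentile 0.03, with 0 of 14 above 0, and HSPA1A was at 19.7 and 12.8 FPKM, and has 73.6% of its sequence in another gene of the table. G1 cyclins and kinases (-0.16), homologous recombination genes (-0.11), telomerase and shelterin components (-0.13) and oxidative phosphorylation genes (-0.12) were also below. The first and the telomerase list were inside the random range by their means, and the recombination list with a mean FPKM of at least 5. Among telomerase and shelterin components, TEP1 was at 5.98 FPKM, a log2 difference of 0.80, and TINF2, a shelterin protein, was at 17.6 and 13.5 FPKM. Inside the random range lay integrated stress response genes (-0.10), beta-catenin targets (-0.14), ribosomal proteins (-0.08), interferon-stimulated genes (0.08), apoptosis regulators (0.07), kinase inhibitors (0.11), acute-phase genes (0.06) and fatty acid synthesis genes (0.02). Beta-catenin targets stood below with either other pseudocount, after scaling to TPM, without the filter and with the trends removed, and integrated stress response genes with a pseudocount of 5 and with the trends removed. Kinase inhibitors and acute-phase genes stood above by their means, apoptosis regulators with a pseudocount of 5 and hepatocyte secreted proteins with a mean FPKM of at least 5. Medians inside the range whose sign differed from that of the mean were those of ZBTB48 targets (0.05), hepatocyte secreted proteins (0.01), glycolysis (-0.02), ribosome biogenesis (-0.02) and housekeeping genes (-0.01). The last 3, and endoplasmic reticulum chaperones (-0.02), changed sign after scaling to TPM.

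The design sets HKR3 overexpression beside TERT knockdown, which raises the question of shared genes, here with the library labelled siTERT and its TERT at control level. Higher in both treated libraries by at least 2-fold were 19 genes, among them CXCL8, AKR1B10, AKR1C2, AKR1C1, CYP1A1, IL32, UBD and CDKN2B. IL32 was at 6.16 FPKM in the control, 36.4 FPKM in the HKR3 library and 19.6 FPKM in the library labelled siTERT. CDKN2B was at 4.24, 34.4 and 10.8 FPKM. Lower in both were 10 genes, among them ASNS, CLEC2L, FAM210B, FHIT, CDC42EP5 and the histone genes H2BC3, H4C4 and H3C13. FAM210B was at 14.5, 4.78 and 6.72 FPKM. Between the treated libraries, HKR3 minus siTERT, the log2 difference was -0.03 for FHIT and H4C4, -0.02 for H3C13 and 0.07 for CDC42EP5. It was -0.88 for CLEC2L, -0.50 for ASNS, -0.42 for FAM210B and 0.46 for H2BC3. Of the higher genes named here, UBD differed by -0.12 and the others by 0.76 or more. Where the treated libraries were nearly equal, a deviation of the single control library cannot be told apart from a shared difference. The number higher in both depended on the settings, with 32 after scaling to TPM, 72 with a pseudocount of 0.1 and 8 with a pseudocount of 5, and the number lower in both was 24 and 1 with these pseudocounts.

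Independent lists of these sizes would share 1.71 higher and 0.553 lower genes, a value that leaves out the shared control. At the settings of the main comparison, unchanged libraries simulated against a shared control shared 0.48 and 0.41, with at most 3 of each. All simulated libraries had the spread of the library labelled siTERT, which is smaller than that of the HKR3 library. These simulated counts are therefore no reference for the 19 and 10 genes, and no conclusion on the shared control is drawn from them. Both differences had the same sign in 66.3% of genes, against a simulated 66.6% with a shared control. Across genes, which are not independent replicates, the differences had a Pearson correlation of 0.47 and a Spearman correlation of 0.46. Sharing the control gave a simulated correlation of 0.50. Equal spread of all simulated libraries fixes this value and the simulated share of equal signs. The real differences had a variance of 0.368 in the HKR3 library and 0.0624 in the library labelled siTERT. Neither simulated value is therefore a reference for these data, and no conclusion is drawn from them. The covariance was 0.0708, against a simulated 0.0309 from the shared control, a difference of 0.0398. The simulated value assumes that the control deviates as much as the library labelled siTERT. A control that carried all of the variance of the siTERT differences would give a covariance of up to 0.0624. With 1 control library the controls could not be split, so how much of the covariance comes from that library is not known. No conclusion is drawn from the difference of 0.0398.

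**Figure D3:**
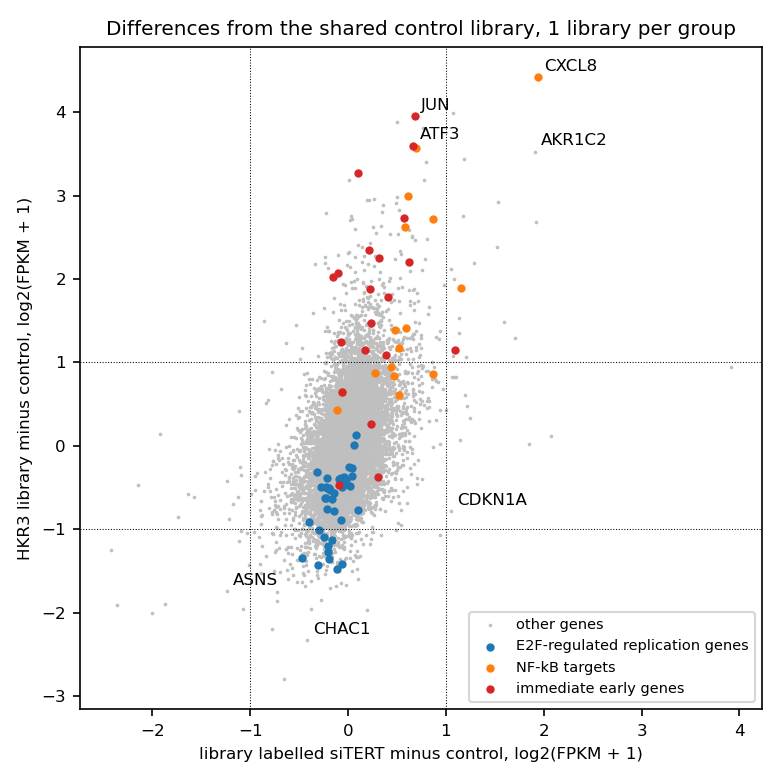
Log2(FPKM + 1) difference from the control of each gene in the HKR3 library (vertical) against that in the library labelled siTERT (horizontal), with dotted lines at 2-fold and ZBTB48 not drawn. Immediate early (red) and NF-kB target genes (orange) lie above 0 on the vertical axis for 18 of 20 and 16 of 16 members, and E2F-regulated replication genes (blue) lie below 0 there for all but 2 of 38 members.

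Set directly against the library labelled siTERT, whose TERT was not lower, the HKR3 library had 451 genes at least 2-fold higher and 150 at least 2-fold lower. Scaling to TPM gave 701 and 131, and a pseudocount of 5 gave 169 and 33. Immediate early genes differed by a median log2 of 1.48 between these libraries and NF-kB targets by 0.72. E2F-regulated replication genes were lower in the HKR3 library by a median of -0.42, at percentile 0, and mitotic genes were higher by 0.15, at percentile 98.9. Polyadenylated histone genes differed by 0.93. CDKN1A was at 8.71 FPKM in the HKR3 library and 33.7 FPKM in the library labelled siTERT.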

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

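The counting and label tests of TERT and the slope test of the paired differences were chosen only after the result was seen. The named genes were searched for opposite differences of at least 1.5-fold in both treated libraries, and 3 genes met this, in each case with a difference between the treated libraries that was not tested. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was below the control in the HKR3 library and above it in the library labelled siTERT, a log2 difference between them of -1.84. The histone genes H2BC4 and H4C8 went the other way, with 1.37 and 1.66. TERT was not lower in the library labelled siTERT.

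TERT was 1.14 times the control in the library labelled siTERT. Counting error is argued against as what hid a knockdown to 0.5 or less, since the lower 95% bound of the ratio on estimated fragments was 0.925. An exchange of labels between the control and this library is argued against for the same size of knockdown, since the reverse ratio had a lower bound of 0.706. Both bounds cover counting error only. A weaker or transient knockdown, a knockdown seen in protein and not in RNA, and a library from outside this set remain open and untested.

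The differences of both treated libraries from the control went together, with a covariance of 0.0708. A deviation of the control library alone would give a slope of the HKR3 differences on those of the library labelled siTERT of at most 1. The 2.5th percentile of the slope over bootstrap draws was 1.07 over all genes and 1.38 among the 6348 genes of at least 10 FPKM. The draws resample genes, which are not independent replicates, so they leave out variation between libraries. The bound over all genes is close to 1, and no conclusion is drawn from it. Among genes of at least 10 FPKM the bound argues against a deviation of the control alone as the whole source. Among the 4625 genes below 10 FPKM the slope was 0.90, with central 95% from 0.82 to 0.99, which a deviation of the control alone allows, so for these it may be the source. Trends with GC content, transcript length and expression are argued against as the whole source, since 93.5% of the covariance was left without them. A response to transfection and an effect common to both treatments remain open, and TERT was not lower in the library labelled siTERT.

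Immediate early and NF-kB target genes were higher in the HKR3 library, with a joint median log2 difference of 1.47 over 35 genes. The same trends are argued against, since the median was 1.64 without them. Sensing of the transfected DNA with an interferon response is argued against only weakly as the whole source. The interferon-stimulated list had a median of 0.31 at percentile 95.3, but only 16 of its 41 genes were measured. Of these, IFIT2, ISG20 and CXCL10 were at least 2-fold higher. A response to plasmid transfection without interferon could not be separated from an effect of HKR3, because whether the control received an empty plasmid is not given in the sources used here.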

How the results depend on the processing

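Removing trends and leaving out genes that share sequence were chosen only after the data were seen. Of the values of counts and of the correlation under alternatives, 61 stayed within the limits set for them and 39 moved, and for what follows the cause was not tested, except that a stricter or looser size rule or filter passes fewer or more genes by construction. A pseudocount of 0.1 gave 487 lower genes in the HKR3 library, 103 higher and 57 lower in the library labelled siTERT, 322 lower in the HKR3 library than in that library, and 72 higher and 24 lower in both. A pseudocount of 5 gave 238 higher and 92 lower genes in the HKR3 library, 10 and 3 in the library labelled siTERT, 169 and 33 between the treated libraries, and 8 and 1 in both. Scaling to TPM gave 991 higher genes in the HKR3 library, 47 in the library labelled siTERT, 701 between the treated libraries and 32 in both, and turned the TERT difference in the HKR3 library from -0.12 to 0.0126. Without the filter, 37 genes were lower in the library labelled siTERT and 20 in both. With a mean FPKM of at least 5, that library had 17 higher and 5 lower genes, and 4 were lower in both. A size rule of 1.5-fold gave 1674 higher and 1393 lower genes in the HKR3 library, 186 and 136 in the library labelled siTERT, 1415 and 1065 between the treated libraries, and 122 and 77 in both. A rule of 4-fold gave 82 and 4, 2 and 4, 55 and 4, and 0 and 1 in the same order.

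Of the list values, 272 for the HKR3 library kept their call and direction, 10 lost the call, 3 gained it and 12 moved, against 269, 8, 9 and 11 for the library labelled siTERT. Of the named genes, 244 values kept their side of 2-fold in the HKR3 library and 10 did not, against 197 and 20. With the trends removed, the HKR3 library had 465 higher and 276 lower genes and the library labelled siTERT 31 and 17. Without genes that share sequence, the counts were 593 and 264, and 21 and 16, with 15 higher and 9 lower in both. TERT was not lower in the library labelled siTERT. No paired analysis was possible because each group has 1 library, and leaving out a library was not possible. Depth limits TERT, whose ratio to the control in the library labelled siTERT had a 95% counting interval from 0.925 to 1.42.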

Other observations

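The set of replication-dependent histone genes was chosen only after the data were seen. These genes, whose transcripts mostly lack a poly(A) tail, numbered 32 with a median mean expression of 2.54 FPKM. Since 5 of them were among the lowest genes named before and prompted the set, these were left out. Of the other 27, 23 were below the control in the library labelled siTERT, in which TERT was not lower, and 5 at least 2-fold lower, with a median log2 difference of -0.44. In the HKR3 library 4 were at least 2-fold higher and 3 at least 2-fold lower, with a median of 0.06 that was -0.13 over all 32. The 27 still hold H4C4 and H3C13, which were named before as lower in both treated libraries. Each is counted among the genes at least 2-fold lower in either library. The 27 are therefore not free of genes already named for low values. Whether the selection of messenger RNA in making the libraries bears on these values was not tested.

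GADD45A, a growth arrest gene chosen after its values were seen, was at 18.3 FPKM in the control, 148 FPKM in the HKR3 library and 21.0 FPKM in the library labelled siTERT, in which TERT was not lower. RB1 was at 15.3, 14.7 and 14.8 FPKM.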
